A study of Homo sapiens with 12 samples.

How the data were processed

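RNA was sequenced from AC16 cells and from the exosomes these cells released. AC16 is an established human line made by fusing primary ventricular cardiomyocytes with transformed fibroblasts, and exosomes are small membrane vesicles that cells secrete. The labels gave 4 groups of 3 libraries each, 12 in all: whole cells and exosomes, each in a group labelled Con and a group labelled Ang. The labels do not spell out Con or Ang. The series' design text gives its purpose as the search for small RNAs in exosomes of hypertrophic cardiomyocytes and for the RNA-binding proteins that can bind them. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Small RNAs and mitochondrial genes were not analysed here.

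Per the labels' protocols, RNA of the cells was extracted with a miRNeasy Micro kit and its libraries were made with a VAHTS Universal kit, while RNA of the exosomes was extracted with an exoRNeasy Maxi kit and its libraries were made with a SMARTer Stranded Total RNA kit. Compartment and kit therefore went together in every library. The deposited values were whole-number read counts per Ensembl gene and, for circular RNAs (circRNAs, closed by back-splicing of an exon end to an earlier exon start), counts of reads across the back-splice junction, per the file headers. The submitters' processing notes name the genome build GRCh38 and the tools HISAT2 and StringTie, without versions or roles. The counting step, the use of strand, the annotation release and the circRNA caller are not given in the sources used here. Each listed gene had at least 7 reads over the 6 libraries of its compartment and each nonzero junction count was at least 2, so that a single junction read is listed as 0. Nearly all listed genes were protein-coding (15344 of 15381 in cells and 11952 of 11973 in exosomes). Symbols were matched for 15365 and 11963 of these genes, and GENCODE release 29 coordinates on GRCh38, counted from 1, for 15362 and 11959. Reads of overlapping genes, of antisense partners and of near-identical copies may be shared, since the handling of such reads is not stated. Host genes of circRNAs were assigned from GENCODE release 29 by position.

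Gene counts were tested with edgeR 4.0.16 (quasi-likelihood F test, trimmed mean of M-values scaling, robust estimation of the spread) in R 4.3.3, after filterByExpr with a minimum count of 10 and a minimum total of 15. All tests were two-sided unless said otherwise, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. Ang was compared with Con within the 6 cell libraries and within the 6 exosome libraries. Over all 12 libraries and the 11940 genes listed in both compartments, exosomes were compared with cells, and the Ang against Con change was compared between compartments. CircRNA counts were tested in the same way within each compartment. Fold changes in the text are fitted values, with the standard error (SE) on the log2 scale and 3 libraries per group. CPM values carry the trimmed mean scaling, except for totals of back-splice junction reads, which were scaled to raw totals of gene reads.

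The tests, 28 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered fetal hypertrophy genes, cardiomyocyte sarcomere and calcium genes, hypertrophic signalling, the renin-angiotensin system, immediate-early genes, fibrosis and extracellular matrix, inflammation, the interferon response and oxidative stress. They also covered the unfolded protein and integrated stress responses, heat shock, hypoxia and glycolysis, nuclear oxidative phosphorylation, the mitochondrial genome, the G1/S and G2/M phases of the cell cycle, p53 targets and senescence, cholesterol synthesis and replication histones. The others were ribosomal proteins, vesicle biogenesis and markers, RNA-binding proteins of small RNA sorting, microRNA biogenesis, circRNA formation and decay, and markers of endothelial, fibroblast, immune, and blood and serum cells. Lists with at least 4 tested members were tested with camera in limma 3.58.1 (preset correlation of 0.01 between genes), beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the lists. The rule named up to 10 higher and 10 lower genes by fold among those past the threshold, without overlap between the groups and with a mean at or above the median, or the 10 genes with the smallest p where fewer than 5 passed. It also named up to 4 passing members of each list, or up to 2 of its most abundant members where none passed, and 13 fixed genes of hypertrophy, small RNA sorting and vesicles.

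Group totals were compared by exact permutation tests, for which 3 libraries against 3 cannot give a two-sided p below 0.1. Correlations across genes or circRNAs used 100000 permutations, and genes are not independent replicates. A group without reads was bounded against a floor of 3 counts over the group. Ratios with 1 to 3 counts carry a 95% exact binomial interval, and such bounds and intervals cover counting error only. Random lists for comparison, 10000 per list, were matched on mean expression, exon length and GC content by drawing from the 50 nearest genes. A drop was defined as a library more than 4-fold below the gene's median scaled level, in genes with a median of at least 40 reads. For leaving genes out and for naming genes with drops, the third-highest library took the place of the median, a rule that also takes in genes whose groups differ by more than 4-fold.

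The alternatives were DESeq2 1.42.0, upper-quartile factors, quantile normalization, median centring, no filter and a filter of 5 reads in 3 libraries, a minimum fold, limma without robust and trend options, all 12 libraries in 1 fit, the replicate number as a block, and each library left out in turn. After the data were seen, edgeR without robust estimation, DESeq2 for the comparisons across compartments, leaving out genes with drops, total gene reads as the circRNA library size, and quantile normalization of the lists were added. The edgeR fits were tested on simulated counts drawn from the real means, spread and library sizes with 200 genes changed, 20 circRNAs in cells. Camera was tested on such counts with a shift of the immediate-early list. The other steps were not tested on simulated counts, and drops were not simulated as such. Of genes changed 4-fold, the cell comparison recovered 78.8%, the exosome comparison 22.7%, the comparison of exosomes with cells 84.8% and the comparison of changes between compartments 10.6%, while 2-fold changes were recovered in 32.8%, 1.49%, 25.4% and 0%. Of the circRNAs changed 4-fold, 4 of 6 were recovered in cells and 0 of 1 in exosomes, too few to give a rate. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.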

Results

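RNA from AC16 cells and from their exosomes was counted in 12 libraries, 3 in each of 4 groups: cells labelled Con, cells labelled Ang, exosomes labelled Con and exosomes labelled Ang. The cell libraries held 9202471 to 11212674 gene reads over 15381 listed genes. The exosome libraries held 717263 to 745311 gene reads in Con and 535442 to 587783 in Ang over 11973 listed genes. Exosome libraries were thus shallower, and their biological coefficient of variation (0.401 in Con and 0.45 in Ang) was above that of the cells (0.23 and 0.225). Libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 24.2 to 25.8 in cells and 7.61 to 8.1 in exosomes, so none was treated as 1 library deposited again. This does not show that they came from separate cultures. In cells, 298 of 11570 genes with a median of at least 40 reads (2.58%), and in exosomes 382 of 3454 (11.1%), had at least 1 library more than 4-fold below the gene's median, which is called a drop here.

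The cells labelled Ang were compared with the cells labelled Con to find which genes differed with the label. FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230) encodes a subunit of the AP-1 transcription factor. It stood at 64.6 ± 3.33 CPM in Ang and 24.6 ± 2.64 in Con (SD, n = 3 each), 2.62-fold higher (log2 1.39, SE 0.102). Its reads were 601, 687 and 648 against 213, 228 and 310. Immediate-early genes, which cells transcribe within minutes of a stimulus, rose as a group with the preset correlation between genes. Of the 29 members tested, 27 had a positive fold change and the median was 1.18-fold (log2 0.24; camera, Benjamini-Hochberg adjusted p = 3.04e-10). The call was lost with an estimated correlation (adjusted p = 0.203), and fry gave an adjusted p of 0.0227. With edgeR no member passed over all genes tested, while 6 rose when adjusted over the list alone. These were FOS and the zinc finger factor genes EGR1 (1.31-fold, log2 0.39, SE 0.0516), EGR3 (log2 1.36, SE 0.327) and KLF4 (log2 0.50, SE 0.0967). The others were the stress-induced factor gene ATF3 (log2 0.47, SE 0.0873) and the MAP kinase phosphatase gene DUSP5 (log2 2.01, SE 0.416). JUN, which encodes the partner of FOS in AP-1, had a log2 fold change of 0.60 (SE 0.181) and did not pass over the list. With DESeq2, another test of the same counts, FOS, EGR1, DUSP5 and ATF3 passed over all genes (adjusted p = 5.04e-23, 1.32e-05, 0.00417 and 0.0396).

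**Figure D1:**
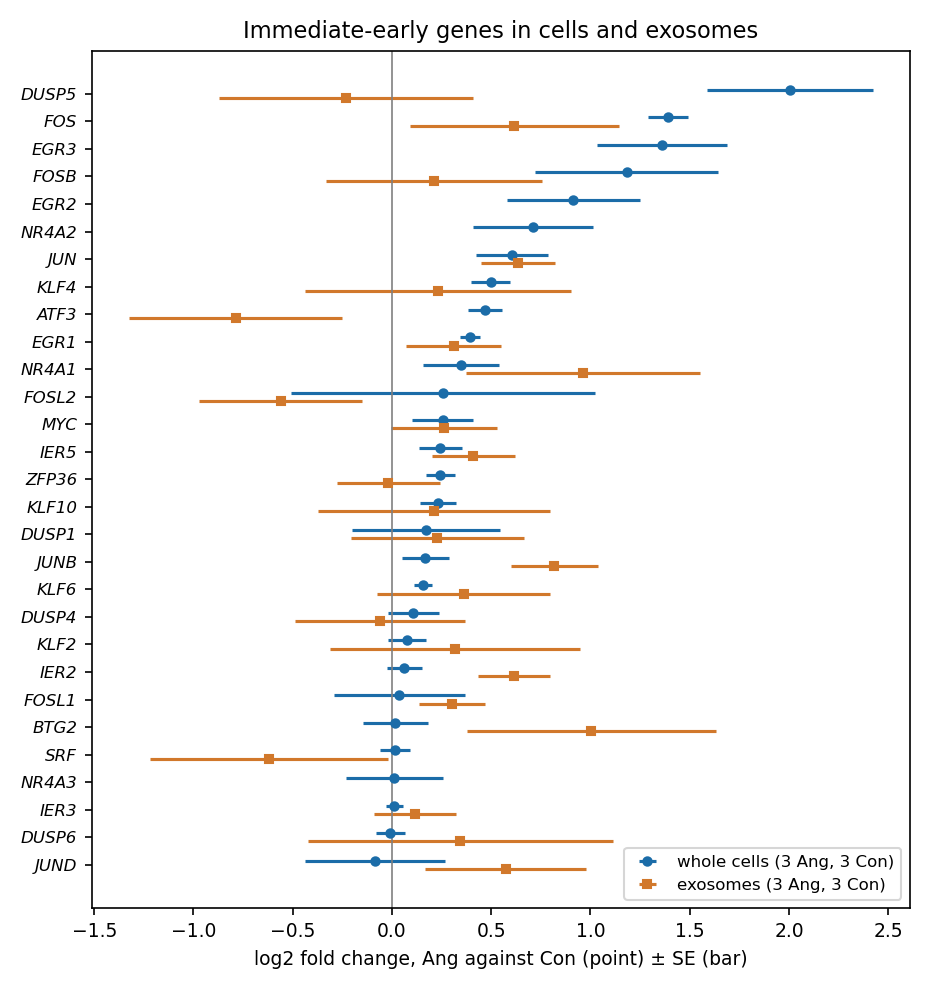
Log2 fold changes of the immediate-early genes between Ang and Con, in cells and in exosomes, with 3 libraries per group and bars for 1 SE. In cells 27 of 29 members lay above 0 and in exosomes 19 of 25.

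Ribosomal protein genes in cells shifted by a small amount in the same direction, with 62 of 79 members positive and a median of 1.04-fold (log2 0.05; camera, adjusted p = 2.61e-05). That call was also lost with an estimated correlation (adjusted p = 0.449) and with fry (adjusted p = 0.125), and no ribosomal gene passed over all genes or when adjusted over the list alone. Lists matched on mean expression, exon length and GC content had a median of log2 0.03 (central 95% 0.009 to 0.05). Markers of cardiac hypertrophy did not pass. The natriuretic peptide gene NPPA had 10, 15 and 10 reads in Ang and 14, 11 and 26 in Con (log2 -0.51, SE 0.357). The cardiac ankyrin repeat gene ANKRD1 had a log2 fold change of 0.30 (SE 0.14), and the calcineurin regulator gene RCAN1 one of 0.03 (SE 0.0967). NPPB and ACTA1 were under the count filter, and MYH7 was not analysed here. AGTR1, which encodes the type 1 angiotensin II receptor, had a log2 fold change of -0.05 (SE 0.158). The collagen gene COL1A1 (log2 -0.20, SE 0.037) and the mitochondrial superoxide dismutase gene SOD2 (log2 -0.93, SE 0.244) did not pass. The vesicle tetraspanin genes CD63 (log2 0.08), CD81 (log2 -0.12) and CD9 (log2 -0.06) did not pass. The same held for the RNA-binding protein genes YBX1 (log2 -0.01), HNRNPA2B1 (log2 -0.05) and SYNCRIP (log2 0.11). In the interferon list the antiviral genes IFIT2 (log2 0.39, SE 0.075) and DDX60 (log2 0.37, SE 0.0673) rose when adjusted over the list alone. With edgeR neither passed over all genes, while DDX60 did with DESeq2 (adjusted p = 0.0185). The list did not pass with camera (adjusted p = 0.0872) and passed narrowly with fry (adjusted p = 0.0485).

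Of 13331 genes tested in cells, edgeR called 0 and the smallest Benjamini-Hochberg adjusted p was 0.121. An unadjusted p under 0.05 was found for 816 genes, against 667 expected by chance. DESeq2 called 60, of which 26 were higher in Ang and 34 lower, with 781 at an unadjusted p under 0.05. In other splits of the 6 cell libraries into groups of 3, DESeq2 called up to 49. Its calls alone thus do not set a difference between Ang and Con apart from chance. EdgeR called 3 without the Con library of replicate 3. None of the 10 genes with the smallest p passed with edgeR, and all 10 did with DESeq2. FOS and EGR1 were among them, as were FJX1 (ENSG00000179431, chromosome 11, 35618419 to 35620868; log2 2.41, SE 0.189) and MATCAP1 (8-fold lower, SE 0.29). The rest were PACS1 (log2 1.08, SE 0.12), SCYL2 (log2 0.84, SE 0.107), APPBP2 (log2 0.74, SE 0.097), with positive changes, and TBC1D8 (log2 -0.77, SE 0.0845), the ciliary transport gene IFT140 (log2 -1.48, SE 0.189) and the RNA helicase gene DDX17 (log2 -0.76, SE 0.102), with negative ones. FJX1 and MATCAP1 were among the genes with drops, by the rule that also takes in genes whose groups differ by more than 4-fold. Of 26 lists tested in cells, those other than the immediate-early and ribosomal protein genes had adjusted p-values of 0.0872 to 0.921. Median and mean differed in sign for the fetal hypertrophy genes (log2 0.02 and -0.04), the replication histones (0.04 and -0.01), the fibroblast markers (-0.08 and 0.02) and the immune markers (-0.03 and 0.22).

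In exosomes, the question was which RNAs differed between vesicles of the Ang and Con groups. TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600) encodes an inhibitor of thioredoxin that restrains glucose uptake. It fell from 126, 165 and 111 reads in the Con exosomes to 0, 1 and 0 in the Ang exosomes. The ratio of Con to Ang was 306 (95% counting interval 54.6 to 12100). The fitted log2 change of -7.85 (SE 0.635; edgeR, Benjamini-Hochberg adjusted p = 0.00216) depended on the prior count, and was log2 -9.91 without the Ang library of replicate 2, which held the read. With the preset correlation the immediate-early genes rose as a group in the Ang exosomes, with 19 of 25 members positive and a median of 1.23-fold (log2 0.30; camera, adjusted p = 0.0163). The call was lost with an estimated correlation (adjusted p = 0.45). Across these 25 genes, which are not independent replicates, no relation was detected between the fold changes in cells and exosomes (Pearson r -0.125, permutation p = 0.547; Spearman rho -0.135, permutation p = 0.517). No member passed, over all genes or when adjusted over the list alone, and JUN had a log2 fold change of 0.63 (SE 0.186). The call of the list was also lost without the Con library of replicate 1 (0.0872) or 2 (0.0937) or the Ang library of replicate 1 (0.153) or 2 (0.091).

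The heat shock gene HSPA1B rose in the Ang exosomes when adjusted over its list alone (log2 0.60, SE 0.115; edgeR, Benjamini-Hochberg adjusted p = 0.00509 over the list and 0.296 over all genes). The reads of HSPA1B and its near-identical copy HSPA1A cannot be separated with confidence. The other genes with the smallest p did not pass with edgeR, and all 10 with the smallest p, TXNIP included, did with DESeq2. COASY, a gene of coenzyme A synthesis, had a log2 fold change of -3.30 (SE 0.447), the retinoic acid induced gene RAI1 one of 2.38 (SE 0.336), and PABPC1L one of 4.43 (SE 0.71). The log2 fold changes were -2.11 (SE 0.363) for CYTH2 and -2.94 (SE 0.538) for the semaphorin receptor gene NRP1. The syntaxin gene STX4 had a log2 fold change of 2.23 (SE 0.412), DNAJC21 of -2.51 (SE 0.468) and ZNF598 of -1.93 (SE 0.36). BMPR2, which encodes a bone morphogenetic protein receptor, had 20, 62 and 105 reads in Con and 0 in each Ang library. It was at least 47.4-fold lower against a floor of 3 counts over the group. CD63 (log2 -0.12), CD81 (log2 -0.23), CD9 (log2 -0.02), YBX1 (log2 0.02) and HNRNPA2B1 (log2 -0.89, SE 0.549) did not pass. TXNIP, COASY, RAI1, NRP1, DNAJC21, ZNF598, CD81 and HNRNPA2B1 were among the genes with drops. The rule for this also takes in genes whose groups differ by more than 4-fold.

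Of 8327 genes tested in exosomes, edgeR called 1. An unadjusted p under 0.05 was found for 316, fewer than the 416 expected if p-values were evenly spread. Other splits of the 6 exosome libraries into groups of 3 gave 215 to 279. The splits number 10, too few for a share under 0.05. DESeq2 called 16 (5 higher, 11 lower), the fit to all 12 libraries 22, and edgeR without the low-count filter 3. In other splits of the exosome libraries DESeq2 called up to 19, more than in the real one. Its calls alone thus do not set a difference apart from chance here either. Of 23 lists tested in exosomes, the others had adjusted p-values of 0.568 to 0.958. Median, mean and test differed in sign for the fetal hypertrophy genes (log2 median -0.08, mean 0.09), the extracellular matrix genes (-0.04 and 0.05), the vesicle genes (-0.05 and 0.05) and the ribosomal protein genes (0.0025 and -0.0065). For the heat shock genes, the median (-0.07) and mean (-0.05) were negative while the test pointed up.

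Whether the Ang against Con change differed between exosomes and cells was tested in the fit to all 12 libraries. TXNIP did, with a change in exosomes minus that in cells of log2 -8.13 (SE 0.528; edgeR, Benjamini-Hochberg adjusted p = 1.74e-05). With 1 read in the Ang exosome libraries this value depended on the prior count, and it was log2 -13.15 without the Ang exosome library of replicate 2. In cells, TXNIP had 3473 to 4241 reads in Con and 3486 to 3643 in Ang (log2 -0.09, SE 0.0656). EIF2AK3 (ENSG00000172071, chromosome 2, 88556741 to 88627576), which encodes the PERK sensor of unfolded proteins, differed by log2 -3.67 (SE 0.505, adjusted p = 0.0293). It had 15, 20 and 19 exosome reads in Con and 1 in each Ang library, a ratio of 13.7 (95% counting interval 4.44 to 68.4). RAI1 (ENSG00000108557, chromosome 17, 17681473 to 17811453) differed by log2 2.37 (SE 0.321, adjusted p = 0.0293). It had 20, 36 and 22 exosome reads in Con and 93, 128 and 90 in Ang, and its change in cells was log2 0.01 (SE 0.0733). In the fit to the exosome libraries alone, RAI1 had log2 2.38 (SE 0.336; edgeR, adjusted p = 0.102) and did not pass. EIF2AK3 had log2 -3.64 (SE 0.846, adjusted p = 0.708) there and did not pass either. The fit to all 12 libraries shares 1 estimate of the spread between the compartments, and the cells were the less variable.

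TXNIP, EIF2AK3 and RAI1 were the 3 genes called of 11811. An unadjusted p under 0.05 was found for 971 genes, against 591 expected by chance. Without any 1 of the 6 cell libraries it was found for 536 to 556, of 10238 to 10250 genes tested. No list of 25 passed (camera, smallest adjusted p 0.427). The calls of RAI1 and EIF2AK3 were lost without any 1 of the 6 cell libraries (edgeR, adjusted p 0.0785 to 0.13 over both genes) or without the Con exosome library of replicate 3 (0.0645 and 0.0578). Leaving out a cell library also moved the count filter, which scales with the median library size, so fewer genes were tested. The folds changed little there (log2 2.32 to 2.42 for RAI1 and -3.60 to -3.76 for EIF2AK3). The share of the filter in these losses was not tested. DESeq2 called 368 genes. Across the 8316 genes tested in both compartments, which are not independent replicates, no relation was detected between the fold changes in cells and exosomes (Pearson r 0.00226, permutation p = 0.835; Spearman rho 0.00379, permutation p = 0.73). Median and mean of the difference had opposite signs for hypoxia and glycolysis (log2 0.05 and -0.03), p53 targets (-0.05 and 0.15), histones (0.002 and -0.03), microRNA biogenesis (-0.05 and 0.17) and fibroblast markers (0.19 and -0.03).

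Exosomes were compared with cells to find which RNAs the vesicle libraries held in excess or in deficit. RAB13 (ENSG00000143545, chromosome 1, 153981617 to 153986358) encodes a small GTPase of vesicle transport. It stood at 7265 ± 552 CPM in exosomes and 109 ± 25.3 in cells (SD, n = 6 each), 67-fold higher (log2 6.07, SE 0.15; edgeR, Benjamini-Hochberg adjusted p = 4.49e-11). Of its exon length, 24.8% is shared with another gene on the same strand. The RhoA exchange factor gene NET1 (29.8-fold, log2 4.90, SE 0.0562), the kinesin adaptor gene TRAK2 (29.2-fold, log2 4.87, SE 0.0634) and the kinesin gene KIF1C (31-fold, log2 4.96, SE 0.77) were also higher. KIF1C was among the genes with drops. DDIT3, which encodes the stress factor CHOP, was 68.5-fold higher (log2 6.10, SE 0.206), with 31.6% of its exon length shared with a gene on the other strand. Lower in exosomes was the calcium pump gene ATP2B1 (70.3-fold lower, log2 -6.14, SE 0.207). The fatty acid desaturase gene SCD was also lower (82.6-fold, log2 -6.37, SE 0.845). It had 124, 190 and 0 reads in Con and 0, 5 and 0 in Ang exosomes. The size of its fitted fold thus rested on libraries with few or no reads and is uncertain. The mitotic kinesin gene KIF14, the RNA-binding protein gene IGF2BP1 and BMPR2 also passed as lower, but 1 exosome group held 0 to 2 reads of each, so their fitted folds depended on the prior count. KIF14 had 4, 6 and 0 reads in Con exosomes and 0 in each Ang exosome library, against 1417 to 1819 in the cell libraries. IGF2BP1 had 2, 1 and 13 and then 1, 1 and 0, against 355 to 1649 in cells. BMPR2 stood at 92.5 ± 64.5 CPM in Con exosomes and 198 ± 7.31 in Con cells (SD, n = 3 each), with 0 reads in Ang exosomes and 190 ± 5.4 CPM in Ang cells.

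**Figure D2:**
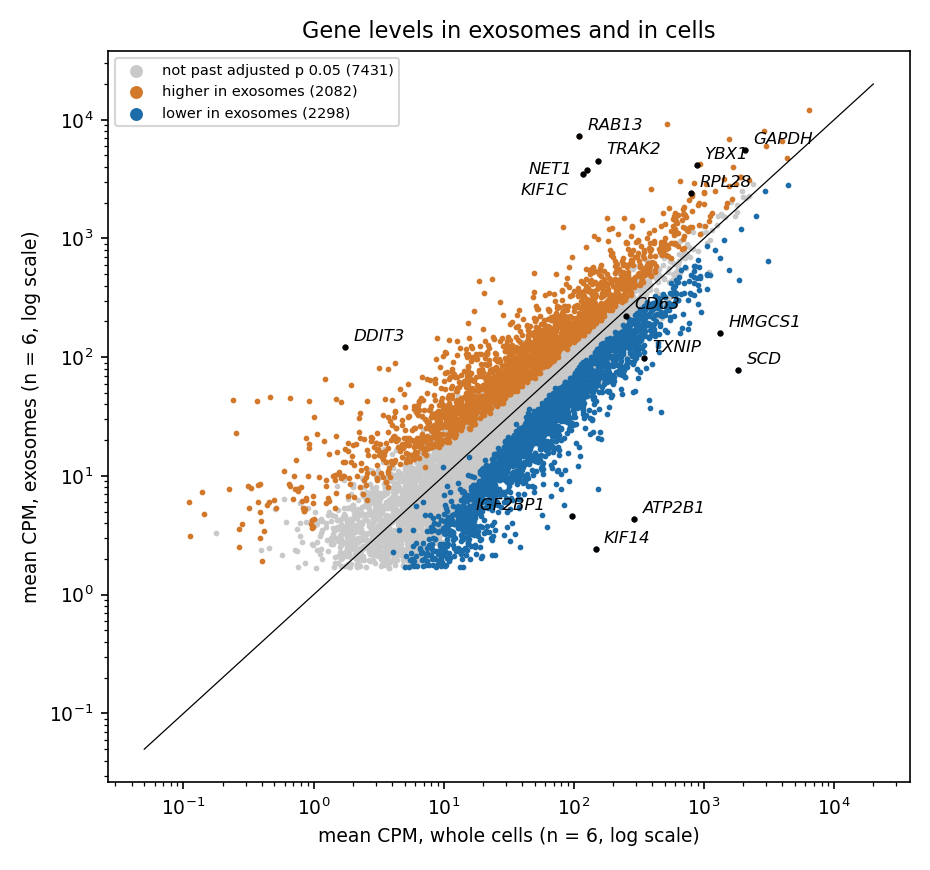
Mean CPM of each tested gene in the 6 cell libraries (horizontal, log scale) and the 6 exosome libraries (vertical, log scale), with the line of equal level. Of 11811 genes, 2082 were higher in exosomes and 2298 lower, with RAB13, TRAK2, NET1 and KIF1C far above the line.

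Messenger RNAs of ribosomal proteins rose in exosomes, 73 of 79 members over all genes and 75 when adjusted over the list alone. Their median was 1.77-fold (log2 0.82; camera, adjusted p = 7.2e-41, and adjusted p = 0.000953 with an estimated correlation). Lists matched on mean expression, exon length and GC content had a median of log2 0.39 (central 95% 0.17 to 0.60). The ribosomal genes included RPL28 (log2 1.60, SE 0.0546), RPL13 (2.82-fold, SE 0.0573) and RPL19 (log2 1.46, SE 0.0536). Genes of cholesterol synthesis fell, 18 of 24 over all genes and 19 adjusted over the list alone. Their median was 2.46-fold lower (log2 -1.30; camera, adjusted p = 1.01e-07, and adjusted p = 0.00262 with an estimated correlation). They included HMGCS1 (log2 -3.06, SE 0.122), which makes the precursor of mevalonate, the squalene synthase gene FDFT1 (log2 -1.59, SE 0.0816), FDPS (log2 -1.53, SE 0.116) and IDI1 (log2 -1.40, SE 0.114). INSIG1, a sterol sensor gene outside the list, had a log2 fold change of -3.76 (SE 0.62). Immediate-early genes rose, 15 of 29 with 2 lower over all genes and 16 with 2 lower adjusted over the list alone. Their median was 2.28-fold (log2 1.19; camera, adjusted p = 1.84e-05, and adjusted p = 0.00567 with an estimated correlation). JUNB (log2 2.94, SE 0.141), IER2 (log2 2.23, SE 0.115), IER5 (log2 1.81, SE 0.134) and ZFP36 (log2 1.47, SE 0.136) were higher, and KLF6 (log2 -1.37) and DUSP6 (log2 -1.73) were lower. Matched lists had medians of log2 0.04 (central 95% -0.35 to 0.42) for cholesterol synthesis and 0.16 (-0.20 to 0.54) for immediate-early genes. With quantile normalization, 53 ribosomal protein genes were higher and 3 lower (median log2 0.49), and the medians of the cholesterol list (log2 -1.40) and the immediate-early list (log2 1.03) had the same sign. With median centring the medians were log2 0.92 for ribosomal proteins, -1.35 for cholesterol synthesis and 0.75 for immediate-early genes.

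The calls of 7 more lists were lost with an estimated correlation. Genes of oxidative phosphorylation (21 of 45 rose, 5 fell; COX5A log2 1.76, COX4I1 log2 1.66), mitosis (11 of 31 rose, 2 fell; CDC20 log2 1.45, CCNB2 log2 1.25) and the p53 response (9 of 22 rose, 1 fell; CDKN1A log2 1.67) passed with camera. Their adjusted p-values were 0.000104, 0.0039 and 0.0253, and each had an adjusted p of 0.062 with an estimated correlation. Hypoxia and glycolysis genes passed too (11 of 27 rose, 4 fell; adjusted p = 0.0253, and adjusted p = 0.062 with an estimated correlation). So did heat shock genes (6 of 14 rose, 1 fell; HSPA1A log2 2.70, HSPA1B log2 2.59; adjusted p = 0.0253, and adjusted p = 0.141 with an estimated correlation). With quantile normalization the medians of these last lists turned negative (log2 -0.17 and -0.06). They and the mitosis list no longer passed (camera, adjusted p = 0.843, 0.679 and 0.138). The median of the p53 list, log2 0.44 in the main fit, moved to 0.02 with median centring. Replication histones were lower (3 of 57 rose, 22 fell; H1-5 log2 -1.13, H1-3 log2 -1.28; adjusted p = 0.00314, and adjusted p = 0.062 with an estimated correlation). G1/S genes were lower too (4 of 30 rose, 14 fell; MCM6 log2 -1.47, MCM3 log2 -0.97; adjusted p = 0.0376, and adjusted p = 0.106 with an estimated correlation). Over the list alone these counts were 22 and 6, 11 and 2, 9 and 2, 12 and 6, 6 and 1, 3 and 23, and 4 and 15, in the order given.

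The genes of vesicle biogenesis and markers went both ways (5 of 30 rose, 6 fell, and 5 and 7 over the list alone) and did not pass as a list (camera, adjusted p = 0.427). The ESCRT gene CHMP4B was higher (log2 1.17, SE 0.0766), the flotillin gene FLOT1 (log2 -1.39, SE 0.178) and the lysosomal membrane gene LAMP2 (log2 -1.08, SE 0.168) were lower. The tetraspanin genes CD63 (log2 -0.16, SE 0.0979), CD81 (log2 -0.08, SE 0.334) and CD9 (log2 -0.04, SE 0.141) did not pass. The RNA-binding proteins of small RNA sorting also split (11 of 39 rose, 8 fell, and 12 and 9 over the list alone; adjusted p = 0.507). YBX1 (log2 2.23, SE 0.147) and the nucleolin gene NCL (log2 2.13, SE 0.113) were higher and HNRNPH1 was lower (log2 -1.67, SE 0.218). HNRNPA2B1 (log2 -0.41, SE 0.329) and SYNCRIP (log2 -0.26, SE 0.491) did not pass. Both were among the genes with drops, as was CD81.

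The other lists did not pass between exosomes and cells (camera, adjusted p 0.155 to 0.875). Their members higher and lower in exosomes numbered 3 and 0 of 9 fetal hypertrophy genes, 1 and 2 of 7 sarcomere and calcium genes, 6 and 5 of 27 hypertrophic signalling genes, and 0 and 3 of 7 renin-angiotensin genes. They numbered 7 and 12 of 33 matrix genes, 7 and 1 of 19 inflammation genes, 2 and 6 of 23 interferon genes, 4 and 6 of 20 oxidative stress genes, and 8 and 3 of 24 unfolded protein and integrated stress genes. The remaining counts were 1 and 5 of 18 microRNA biogenesis genes, 3 and 9 of 22 circRNA formation genes, 0 and 0 of 4 endothelial markers, and 1 and 2 of 8 fibroblast markers. Adjusted over the list alone, the counts differed for matrix (7 and 13), inflammation (8 and 1), oxidative stress (5 and 7), microRNA biogenesis (1 and 4) and circRNA formation genes (3 and 10). Immune markers (0 and 0 of 2, and 1 and 0 over the list alone) and blood and serum markers (1 and 0 of 1) had too few members for a test, and the mitochondrial genome was not analysed here. The collagen genes COL6A1 (log2 1.51) and COL6A2 (log2 1.74) were higher while COL12A1 (2.83-fold lower) and the matricellular gene CCN1 (log2 -1.70) were lower. Median and mean differed in sign from the test for sarcomere genes (log2 -0.16 and -0.11, test up) and RNA-binding proteins of small RNA sorting (-0.06 and -0.14, test up), and from each other for oxidative stress genes (0.07 and -0.02).

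Of the genes compared between compartments, 5461 had an unadjusted p under 0.05. Other genes named by the fixed rule were higher (ATG2A log2 4.84, PPP1R9B log2 4.68, C13orf46 log2 4.32). NBPF20 (log2 4.56) and NOTCH2NLA (log2 4.44) were also higher but have near-identical copies and so are uncertain. Others were lower (PRRC2B log2 -4.09, PRKD3 log2 -3.90). TXNIP and TICRR also passed as lower, but each had 1 read in the 3 Ang exosome libraries together. In the Con group TXNIP stood at 197 ± 40.1 CPM in exosomes and 353 ± 19.9 in cells, and TICRR at 14.8 ± 8.53 and 148 ± 28.1 (SD, n = 3 each). The kits of cells and exosomes differed, so compartment and kit cannot be told apart in any of these differences. The median log2 fold change of all genes was -0.14 and moved to -0.24 with median centring and -0.09 with quantile normalization. Across 11799 genes the fold change was related to exon length (Spearman rho -0.213) and to GC content (rho 0.29).

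CircRNAs were counted to compare what both compartments held. Exosome libraries had 1746 ± 117 back-splice junction reads when scaled to the CPM of gene reads, and cell libraries 719 ± 22.7 (SD, n = 6 each). This scale used raw totals of the listed gene reads, without the trimmed mean scaling of the other CPM values. The difference was 2.43-fold (exact permutation test, two-sided, p = 0.00216), with the kits differing between them. A circRNA of CDYL, a chromatin reader gene (chromosome 6, 4891713 to 4892379, both ends on exon boundaries), was among the most abundant in both. It had 121 ± 22.6 reads in Con and 145 ± 23.7 in Ang cells and 20.3 ± 10.4 and 23.3 ± 14.6 in exosomes (SD, n = 3 each). Circles of the mannosidase gene MAN1A2 (chromosome 1, 117402186 to 117420649, both ends on exon boundaries) had 138 ± 28.4 and 133 ± 10.4 reads in Con and Ang cells and 14 ± 3 and 16 ± 14.7 in exosomes. In exosomes a circRNA of CIZ1 (chromosome 9, 128169052 to 128180799) had 18.3 ± 2.52 and 17 ± 21.7 reads. Of the 939 circRNAs found in exosomes, 418 were among the 5179 of the cells (44.5%, 95% exact interval 41.3 to 47.8). Across these 418, the levels were related (Pearson r 0.477, Spearman rho 0.396 on log2 values, each with permutation p = 1e-05, the smallest 100000 permutations can give).

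**Figure D3:**
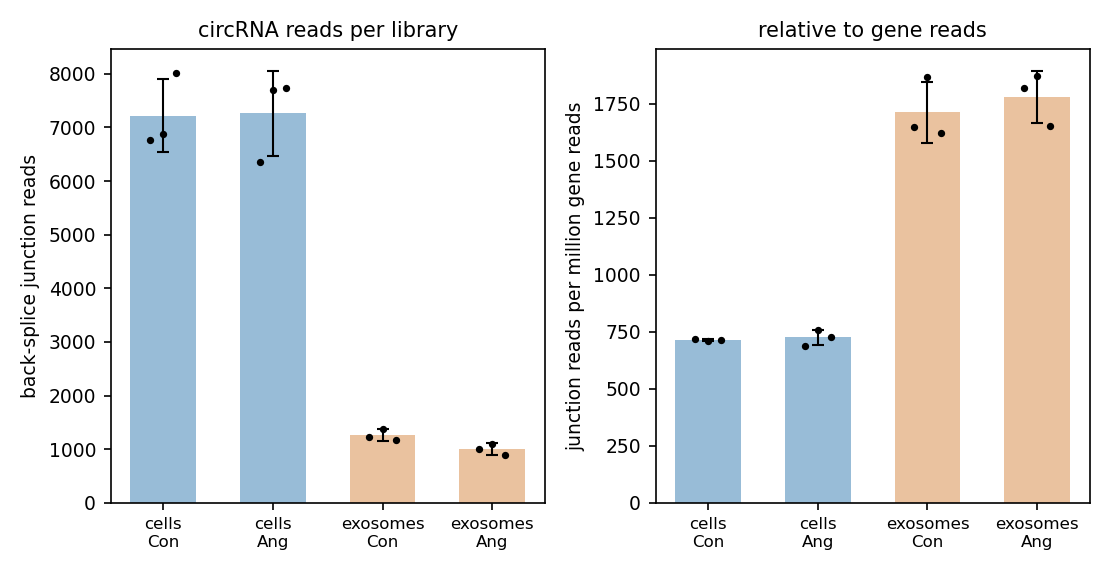
Back-splice junction reads in each of the 12 libraries, as counts (left) and on the CPM scale of raw gene read totals (right). The mean and SD of each group of 3 are shown. The 6 exosome libraries all lie below the 6 cell libraries on the left and above them on the right.

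No circRNA passed between Ang and Con. In cells edgeR called 0 of 97 tested, 2 had an unadjusted p under 0.05, and DESeq2 had 0 at that level. Those 2 were the CDYL circRNA (log2 0.28, SE 0.104) and a circRNA of the noncoding gene LINC00632 (chromosome X, 140783175 to 140784659). The latter had 10, 10 and 17 reads in Con and 24, 25 and 15 in Ang. In exosomes edgeR called 0 of 10 tested with 0 at an unadjusted p under 0.05, and DESeq2 had 1 at that level. Most circRNAs were read in a single library, 3812 (73.6%) in cells and 834 (88.8%) in exosomes. Few could thus be tested, and small differences may have been missed. A difference between Ang and Con in junction reads on that scale was not detected in cells (725 ± 34.1 and 714 ± 4.27, exact p = 0.7) or exosomes (1780 ± 115 and 1713 ± 134, exact p = 0.5; SD, n = 3 each). The Ang exosome libraries held 0.793 times the junction reads, 0.811 times the circRNAs and 0.762 times the gene reads of the Con libraries (exact p = 0.1 for each, the smallest possible). No relation was detected between the changes of circRNAs and of their host genes (Spearman rho -0.00707 over 83 circRNAs in cells, permutation p = 0.951; rho -0.128 over 9 in exosomes, permutation p = 0.746).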

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

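In this part the tests of depth, of loss from the cells, of coinciding drops and of other splits were chosen after the results they bear on had been seen, and the test of the difference between compartments was planned. For 3 genes the Ang against Con change differed between exosomes and cells in the fit to all 12 libraries. They were TXNIP (log2 difference -8.13, and -13.15 without the Ang exosome library of replicate 2, which held its 1 read in that group), RAI1 (log2 difference 2.37) and EIF2AK3 (log2 difference -3.67). Of 100 splits of the libraries within the compartments, drawn from 200, 41 gave at least 3 such genes, the real split included, and the highest of the others gave 11, so chance cannot be excluded for the number of calls. Genes at an unadjusted p under 0.05 numbered 971, against 591 expected by chance. Only the real split of the 100 reached 971, but the others gave 781 to 956. Splits without the real labels thus also lay above the expected number, and the margin of the real split was small. A difference cannot be concluded from that number. Without any 1 of the 6 cell libraries the number was 536 to 556, of 10238 to 10250 genes tested. The count filter moved there too, and other splits were not counted.

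TXNIP was nearly absent from the 3 Ang exosome libraries, with 1 read in all, and present in the Con exosomes. Lower depth of the Ang exosome libraries does not account for this, since 306 reads would be present at the Con share, and loss from the cells does not either, since the change in cells was log2 -0.0917 (SE 0.0656). Many genes lost reads in single exosome libraries. Genes low in exactly 3 libraries were counted only where the third-highest library held at least 40 reads. This left out BMPR2 and EIF2AK3, which were also low in all 3 Ang exosome libraries. Of the 18 genes low in exactly 3 of the 6 exosome libraries, 5 had all 3 in 1 group: TXNIP, COASY, NRP1 and THRAP3, low in Ang, and IGF2, low in Con. Without TXNIP, which prompted the test, these were 4 of 17, against 1.8 expected from the number of drops in each library (exact binomial test, one-sided, p = 0.0977). Drops that coincided by chance were thus not excluded and may account for the loss of TXNIP, and a difference in what the vesicles of the Ang group carry stays open and untested.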

How the results depend on the processing

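The cause of a change with the processing was not tested unless said. Added after seeing the data were DESeq2 across compartments, edgeR without robust estimation, leaving out genes with drops, total gene reads as circRNA library size and quantile normalization of the lists. In cells edgeR called 0 genes, DESeq2 60, and edgeR with 1 library left out 0 to 3, the 3 without the Con library of replicate 3. In exosomes the 1 call became 16 with DESeq2, 3 without the low-count filter, 2 with limma without robust and trend options, 22 with all 12 libraries in 1 fit, and 1 to 4 with 1 library left out (2 without Con replicate 2, 4 without Ang replicate 1, 3 without Ang replicate 3). Leaving out genes with drops gave 0, which tests nothing about TXNIP, since the rule takes out genes over 4-fold lower in 1 group. For the difference between compartments the 3 calls became 6 with quantile normalization, 5 with median centring, 368 with DESeq2, 1 to 17 with 1 library left out (17, 12 and 12 without the Ang exosome library of replicate 1, 2 and 3, 8 and 11 without the Con exosome library of replicate 1 and 2, and 1 without the cell libraries Con replicate 1 or Ang replicate 1, 2 or 3) and 0 without genes with drops, where the same rule took out TXNIP and RAI1 by their own change, and EIF2AK3 stayed in and no longer passed. Genes at an unadjusted p under 0.05 for that difference numbered 971, and 536 to 1411 with 1 library left out. With all 12 libraries in 1 fit they numbered 164 in cells and 1495 in exosomes, where the groups share 1 estimate of the spread. With 1 exosome library left out, edgeR called 0 to 2 circRNAs, 1 without Ang replicate 1, 1 without replicate 2 and 2 without replicate 3. Counting only circRNAs read in all 6 libraries, 5 of 6 exosome circRNAs (83.3%, 95% exact interval 35.9 to 99.6) were shared with cells.

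With an estimated correlation 0 lists passed in cells (immediate-early 0.203, ribosomal proteins 0.449), 0 in exosomes (immediate-early 0.45) and 3 between compartments (immediate-early, cholesterol synthesis and ribosomal proteins). The cause was not tested. With fry the ribosomal proteins in cells had an adjusted p of 0.125, the interferon list in cells came to pass (adjusted p 0.0485), and 18 lists passed between compartments. With 1 exosome library left out, 0 to 1 lists passed and the adjusted p of the immediate-early list ran from 0.0415 to 0.153. The labels do not say that a replicate number marks a shared culture. The deviations of same-numbered libraries correlated at -0.044 to -0.0061 within a compartment, and none correlated best with its own number. Between cells and exosomes they correlated at -0.015 to 0.017. With 3 libraries per group, these values gave no sign of pairing but cannot show that no culture was shared. With the replicate number as a block, edgeR called 0 genes in exosomes (TXNIP adjusted p 0.0593, the smallest) and 1, TXNIP, for the difference between compartments, where 442 genes had an unadjusted p under 0.05. Of 113 genes named as passing between exosomes and cells, 9 lost the call in at least 1 of 19 alternatives, and no called result passed in the opposite direction in any alternative. Named genes that had not passed came to pass in at least 1 alternative in 11 cases in cells, 9 in exosomes, 6 between compartments and 8 for the difference between compartments. Between compartments 7 lists lost their call and 8 others gained one in at least 1 alternative. Pseudocount alternatives do not apply to counts and were not run. Of simulated 2-fold changes, 32.8% were recovered in the cell comparison and 1.49% in the exosome comparison, whose libraries were both shallower and more variable; the share of depth in this was not tested.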

Other observations

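In this part the tests of drops, of handling, of the protrusion genes against matched lists, of the library kits and of other splits were chosen after the results they bear on had been seen. The list of messenger RNAs known to localise to cell protrusions was itself written after RAB13, NET1, TRAK2 and KIF1C had been seen at the top of the exosome comparison, so their place there is no independent evidence and they are left out of its counts. Of the other 5 members, 3 were higher in exosomes than in cells, and the median of the 5 was 2.7-fold (log2 1.43). The 3 were the adaptor gene KANK2 (8.88-fold, log2 3.15, SE 0.478), the plakophilin gene PKP4 (3.19-fold, log2 1.67, SE 0.444) and the collagen receptor gene DDR2 (2.7-fold, log2 1.43, SE 0.13), while CYB5R3 (log2 0.71, SE 0.305; edgeR, Benjamini-Hochberg adjusted p = 0.089) and DYNLL2 (log2 0.13, SE 0.264) did not pass.

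A candidate explanation, not tested here, for the higher level of these genes is that the vesicles took up RNA from the cell periphery. Expression level, exon length and GC content do not account for it, since 34 of 10000 lists matched on them had a median as high as that of the 5 (median of the matched lists -0.14, central 95% -0.81 to 1.05). KANK2 and PKP4 had isolated drops. In cells they stood at 13.4 ± 2.79 and 83.8 ± 19.8 CPM, and in exosomes at 119 ± 80.5 and 272 ± 174 (SD, n = 6 each). The wide spread was thus in exosomes, where lost reads lower the level. This argues against drops as the source of the higher level of these 2 genes. The other 3, too few for a test, had a median of log2 0.71. The library kits stay open, because 0 kits were used in both compartments, and compartment and kit cannot be told apart.

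The higher immediate-early genes in the Ang cells may reflect a response to what the label Ang stands for, but the call of the list rests on the preset correlation and was lost with an estimated one (adjusted p = 0.203). Isolated drops do not account for the shift, since without genes that had them camera at the preset correlation gave an adjusted p of 7.19e-10, nor do expression level, exon length and GC content, since 0 of 10000 matched lists had a median as high (central 95% of the matched medians -0.08 to 0.05). Handling of the cultures at harvest, which also induces these genes, stays open: the heat shock list had a median of log2 -0.047 in the same cells, but handling need not move that list. The splits of 6 libraries number 10, too few for a share under 0.05; the real split gave the smallest p (camera, unadjusted, 1.17e-11) and the lowest of the others 0.00199, with the real split the 1 that reached it.

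Other splits of the libraries were counted for each comparison. Between exosomes and cells, 1 of 100 splits, the real one, gave as many genes (4380, highest other 7). The same held for genes at an unadjusted p under 0.05 (5461, highest other 2606). In the other splits the difference between compartments and kits goes into the spread, which holds calls down. These splits therefore cannot by themselves exclude chance differences between a few preparations. As many lists were also given by 1 of 100 splits (10, highest other 9), but there the margin over the other splits was small. For lists with a different change in exosomes and cells, 100 of 100 splits gave at least the real number of 0, and the highest other gave 1. Within a compartment the 10 splits are too few for a share under 0.05. In cells the real values and the highest other were 0 and 2 genes with edgeR, 816 and 521 genes at an unadjusted p under 0.05, 60 and 49 genes with DESeq2, 2 and 1 lists, and 0 and 0 circRNAs. In exosomes they were 1 and 3 genes with edgeR, 316 and 279 genes at an unadjusted p under 0.05, 16 and 19 genes with DESeq2, 1 and 0 lists, and 0 and 1 circRNAs. Both 316 and 279 lay below 416, the number expected if p-values were evenly spread. The other splits of the exosome libraries gave 215 to 279, so 416 is not the level that relabelling gave. Splits with as large a value, the real one included, numbered 10, 1, 1, 1 and 10 in cells and 4, 1, 2, 1 and 10 in exosomes.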
